A study of Homo sapiens with 12 samples.

How the data were processed

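Gene expression was measured in 12 samples of T47D, a human luminal breast cancer cell line that expresses estrogen and progesterone receptors, on 1-colour (Cy3) oligonucleotide arrays, 1 sample per array. Per the labels, cells were kept for 5 days in medium with 5% charcoal-stripped serum, 1 nM estradiol and 10 nM progesterone, and were then sorted by flow cytometry in 2 separate studies. In the first, cells were permeabilized, fixed and stained for cytokeratin 5 (CK5, the protein of KRT5), and CK5+ and CK5− cells were collected. In the second, cells were dissociated enzymatically, stained for the surface receptor CD28, and CD28+ and CD28− cells were collected. The cell type label of all CD28 samples, of both gates, lists CK5+, and the labels do not say whether cells were selected for CK5 before the CD28 gate. Each of the 4 groups had 3 arrays. The labels do not say whether the 3 samples of a group came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

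The scanner files hold, per the file headers, the intensity of each spot as extracted by Feature Extraction, version 10.10.1.1 for the CK5 arrays and 11.5.1.1 for the CD28 arrays, with background already subtracted in the processed signal. The authors also deposited a table of log2 values. Its columns correlated with the log2 processed signal of the same array at r of at least 0.999, its medians were 6.36 in the CK5 arrays and 6.32 in the CD28 arrays, and sorted values of arrays in 1 study differed by at most 0.0268 and 0.0356, so the values were quantile-normalized within each study and not centred per gene. Per the submitters' processing notes Partek was used, with no version given. The deposited log2 table served as an alternative only.

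Each array held 43118 non-control spots of 34127 distinct probes. Spots with an outlier mark were left out, which removed 305 to 407 spots per CK5 array and 165 to 216 per CD28 array; no spot was saturated. Spots of 1 probe were averaged, and 20 probes with no usable spot on some array were left out. Log2 processed signals were scaled by subtracting each array's 75th percentile over probes, so a level of 0 is the 75th percentile of that array. Gene names were taken through transcript accessions from a gene table of assembly GRCh38.p14 for 25771 probes, and 8356 probes kept the name in the files, giving 26123 gene names. Probe positions are those of the files (hg19); whether a probe lies in an exon or an untranslated region is not given in the sources used here. For each gene the probe with the highest mean over the 12 arrays was used. A gene was kept in a comparison if its probe was well above background on at least 3 of the 6 arrays, which left 17683 genes in the CK5 comparison and 21053 in the CD28 comparison.

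Depth on an array is limited by signal over background: 65.8% to 70.6% of spots were well above background on the CK5 arrays and 75.4% to 82.4% on the CD28 arrays. The number of arrays limits the precision. Where a gene was not well above background on any array of 1 group, the difference is given as a bound: the brighter group's mean against, for each array of the dimmer group, the higher of the gene's own signal and the lowest signal among probes well above background. Arrays lay on 4 slides, each holding both groups of a study. Slide 1 held replicate 1 and slide 2 replicates 2 and 3 of the CK5 study, and slide 3 held replicates 1 and 2 and slide 4 replicate 3 of the CD28 study; scan batches followed the slides.

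Groups were compared with limma 3.58.1 (lmFit and eBayes, two-sided) in R 4.3.3, on the 6 arrays of each study, with Benjamini-Hochberg adjustment and a threshold of 0.05. Each log2 difference is the positive minus the negative population, with its standard error (SE). A difference between the 2 sorts was tested as an interaction contrast over all 12 arrays. Sets of genes were tested with camera at a preset correlation of 0.01, beside it with an estimated correlation and with fry, over 23 lists of 799 genes, of which 791 were on the array; p-values were adjusted over the 23 lists of a comparison. The lists were basal and myoepithelial, luminal and steroid receptor, cornified and squamous, estradiol response, progesterone response, retinoid, Notch, Wnt, stem and progenitor, epithelial to mesenchymal, proliferation, replication-dependent histone, immediate early and heat shock, unfolded protein and amino acid stress, hypoxia and glycolysis, cholesterol synthesis, oxidative phosphorylation, ribosomal protein, interferon response, NF-kB and cytokine, lymphoid, myeloid, and fibroblast and endothelial. Samples, tests, lists, the rule for named genes and most alternatives were fixed before the data were examined.

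The rule named KRT5 and CD28 first. It then named per comparison the 10 genes with the largest rise and the 10 with the largest fall past the threshold, with gaps filled by the genes of smallest unadjusted p among those whose groups did not overlap; since 0 genes passed, all these are fillings. Next came up to 4 members per list past the threshold, which was read as the threshold adjusted over the list alone; this reading was chosen after the values were seen. Members of other lists are given as examples of smallest p, also chosen after the values were seen. Last came a fixed panel of keratins, receptors and surface markers. CD24 of that panel is not reported here because the files place its probe away from the gene. Names of accessions, clones and open reading frames were skipped. Of the genes that the rule named, 1 of the CK5 and 1 of the CD28 comparison are not reported here.

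The labels number the replicates of each group. Samples with the same number deviated together from their group means, with correlations across genes of 0.61, 0.69 and 0.18 in the CK5 study and 0.53, 0.53 and 0.62 in the CD28 study. Samples with different numbers gave −0.64 to 0.25 and −0.53 to 0.24. The numbers were therefore taken as pairs, which comes from the data, since no label says what a number shares. Pair 1 of the CK5 study and pair 3 of the CD28 study were each alone on a slide. Their correlations of 0.61 and 0.62 cannot be told apart from an effect of the slide. Deviations from a group mean also cancel within the group, so positive values for the same number force lower ones for different numbers. Pair 3 of the CK5 study is weakly grounded: CK5+ replicate 3 deviated more with CK5− replicate 2 (0.25) than with CK5− replicate 3 (0.18). Values with the replicate number as a block are given where they change a call. Other alternatives were normexp on the mean and background signals with an offset of 50, quantile normalization, median scaling, no filter and a stricter filter on dim probes, probes averaged or each tested, all 12 arrays in 1 fit, eBayes with trend and robust, array weights, the deposited table, the slide as a block and within slides, and each array left out. Removal of both arrays of a replicate number and several settings of the list tests were added after seeing the data, since CK5− replicate 3 stood apart.

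The fits were tested on simulated data drawn from the fitted spreads, 5 simulations with 200 changed genes each. With the pair structure of the data and no block, limma recovered 61.2% of 8-fold, 10.4% of 4-fold and 0% of 2-fold changes over the 17683 genes of the CK5 comparison, and 79.6%, 34.4% and 0% over the 21053 genes of the CD28 comparison. With the block, 8-fold and 4-fold changes were recovered at 80.8% and 41.6% in the CK5 comparison and at 91.6% and 68.8% in the CD28 comparison. Tables were read with Python 3.11.15 and pandas 2.3.3, and plots drawn with matplotlib 3.10.9. An overlap of called genes between the sorts was not computed, since no gene was called.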

Results

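RNA of T47D breast cancer cells sorted by cytokeratin 5 (CK5) or by CD28 was profiled on 12 arrays, 3 for each of the CK5−, CK5+, CD28− and CD28+ populations. CK5 is a keratin of basal epithelial cells that appears in a minority of cells of luminal lines given progestins, and CD28 is best known as a costimulatory receptor of T cells. The comparisons ask how the cells that carry each marker differ in expression from those that do not, under the same 5 days of estradiol and progesterone. The 75th percentile of processed signal over spots ranged from 617 to 1101 on the CK5 arrays and from 480 to 719 on the CD28 arrays, and repeated spots of a probe varied by a coefficient of 3.83% to 5.23%. Levels are log2 signals relative to the array's 75th percentile, and each log2 difference is given with its SE from 3 arrays per group unless stated otherwise.

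Neither sorted marker was measurably higher at the transcript level in the cells sorted for it. The single KRT5 probe (chromosome 12, 52908622 to 52908681, hg19, minus strand) was not well above background on any of the 6 arrays of the CK5 sort, with levels of −7.54 ± 0.42 in CK5− and −7.01 ± 1.43 in CK5+ cells (SD, n = 3), so no fold is given and the gene was not tested. In the CD28 sort the same probe was well above background on 2 of 3 CD28− arrays, at a group mean of −5.02 ± 0.66, and on 0 of 3 CD28+ arrays, at −7.05 ± 1.08 (SD, n = 3). Against the lowest detected signals of the CD28+ arrays the CD28− mean of KRT5 was 1.32-fold higher. This was not tested because fewer than 3 arrays of the study detected the gene. It is not a strict bound, since the mean includes CD28− replicate 3, where KRT5 was not well above background. In replicate 3 the levels were −5.74 in CD28− and −5.80 in CD28+ cells, neither well above background. The cell type label of all CD28 samples, of both gates, lists CK5+, so a selection for CK5 before the CD28 gate stays possible. The brighter of 2 CD28 probes (chromosome 2, 204599903 to 204599962, hg19, plus strand) was well above background on all 12 arrays. Its level was −3.11 ± 0.29 in CD28− and −3.26 ± 0.42 in CD28+ cells (SD, n = 3), a log2 difference of −0.15 ± 0.27 (limma adjusted p = 0.999). In the CK5 sort it differed by −0.18 ± 0.36 (limma adjusted p = 1.00). The other CD28 probe (chromosome 2, 204602450 to 204602509) was well above background on 1 array of the 12, a CK5+ array.

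**Figure D1:**
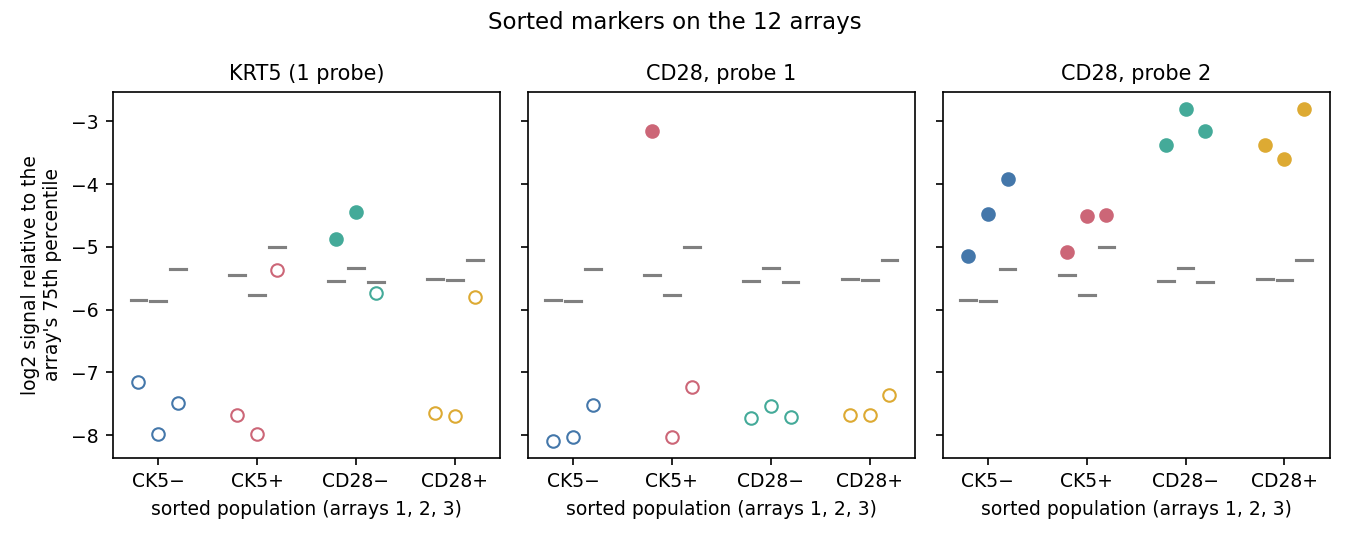
Levels of the KRT5 probe and both CD28 probes on each array (log2 signal relative to the array's 75th percentile), by sorted population, with filled points for probes well above background and grey ticks for the lowest signal among probes well above background on that array. KRT5 is filled on 2 CD28− arrays, and the brighter CD28 probe on all 12 arrays at similar levels in the positive and negative populations of each sort.

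No single gene separated CK5+ from CK5− cells past the threshold. The keratins of luminal cells differed by less than their SE in the fit without the replicate block. Their log2 differences were 0.19 ± 0.45 for KRT8, 0.05 ± 0.34 for KRT18 and −0.07 ± 0.27 for KRT19. KRT8 was higher in all 3 pairs, at 0.07, 0.06 and 0.46. With the block the SEs were 0.18, 0.17 and 0.17, and none of the 3 keratins passed. The steroid receptor genes differed by 0.50 ± 0.54 for ESR1 and 0.82 ± 0.91 for PGR, and the PGR value came from 1 pair, at −0.20, −0.37 and 3.03 in pairs 1, 2 and 3. CD44, a hyaluronan receptor, differed by 0.26 ± 0.31, EGFR by 0.12 ± 0.33 (−0.19 by its other probe) and the proliferation marker MKI67 by −0.29 ± 0.74. Each had an adjusted p of 1.00 by limma. The ESR1 and CD44 values also leaned on CK5− replicate 3. Its ESR1 level was 0.27, against at least 1.75 on the other arrays of the sort, and its CD44 level 3.26, against at least 4.09. The basal genes KRT14, KRT6A, KRT17 and TP63 were well above background on 0, 1, 1 and 0 of the 6 arrays and were not tested.

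Of 17683 genes, 0 passed the threshold by limma (lowest adjusted p = 0.799), and 95 had an unadjusted p under 0.05, 31 higher and 64 lower in CK5+ cells, where chance alone would give 884. The 2 groups did not overlap for 569 genes, or 3.22%, where chance gives 10%. These chance values are for unpaired arrays, and pairs that deviate together lower them. The median SE of a log2 difference was 0.298. With the replicate block limma called 0 genes (lowest adjusted p = 0.885, 221 at an unadjusted p under 0.05), and array weights also gave 0 (lowest adjusted p = 0.292, 682 unadjusted).

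The named genes of this sort therefore stand as values that did not pass, each with an adjusted p of 1.00 by limma, and were chosen among genes whose groups did not overlap, so their agreement over the 3 pairs follows from the choice. Among those lower in CK5+ cells, CDKN2B, a cyclin-dependent kinase inhibitor (chromosome 9, 22008979 to 22009038, hg19), was at least 1.90-fold lower. PREX2, a Rac exchange factor (chromosome 8, 69017538 to 69017597, hg19), was at least 1.92-fold lower, and the antisense RNA RAD21-AS1 at least 1.38-fold lower. P2RX1, an ATP-gated channel whose probe was well above background on 1 of 3 CK5+ arrays, differed by −1.93 ± 0.54, and ALDH3A1, an aldehyde dehydrogenase, by −0.67 ± 0.18. The lipase gene PNPLA2 stood at −0.64, the histone gene H2AC25 at −0.65 and NFYC-AS1 at −0.71. FBRSL1 stood at −0.83, but its 3 probes ranged from −0.83 to 0.24. Genes higher in CK5+ cells were LRRD1 (1.39 ± 0.44), the motilin receptor gene MLNR (1.31 ± 0.40, well above background on 2 CK5+ arrays and 1 CK5− array), RAP1GAP (0.96 ± 0.37), the pseudogene HTATSF1P2 (0.86 ± 0.23) and MFAP5, a microfibril protein gene (0.86 ± 0.25). CPSF2 stood at 0.76, TNFSF9, a ligand of the TNF family, at 0.59, the meiotic gene SYCP1 at 0.55 and PYM1 at 0.50. Probes for pseudogenes and for histone and other multigene families can bind near-identical copies, so HTATSF1P2, H2AC25, DNAJB3 and FAM90A1 are uncertain. The other of 2 probes gave −0.25 for PNPLA2, −0.34 for NFYC-AS1 and 0.52 for RAP1GAP. ALOX15 is given no value, since the probe used was well above background on 0 of 3 CK5− arrays. It is given no bound either, since a bound was taken only where every probe of a gene was dim in a group.

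**Figure D2:**
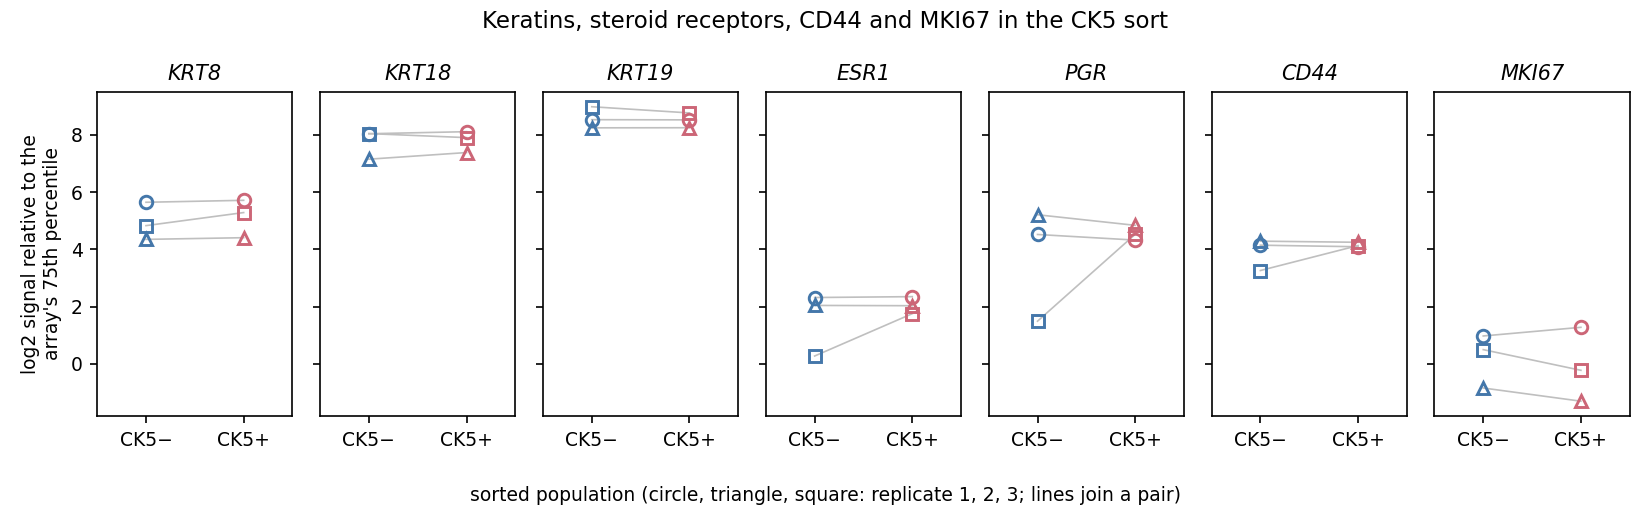
Levels of KRT8, KRT18, KRT19, ESR1, PGR, CD44 and MKI67 on each array of the CK5 sort (log2 signal relative to the array's 75th percentile), with lines joining the 2 arrays of a pair. The ESR1 and PGR points of CK5− replicate 3 lie at 0.27 and 1.49, below the other 5 arrays.

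Among gene groups, 6 of 23 lists passed camera at the preset correlation in the CK5 sort, 5 higher and 1 lower in CK5+ cells. Ribosomal protein genes were higher for 53 of 53 measured members, with a median of 0.42 (1.34-fold, adjusted p = 1.75e-20, and adjusted p = 0.751 with an estimated correlation), for example RPS23 at 0.52 and RPL12 at 0.52. Genes of the unfolded protein response and amino acid stress were higher for 27 of 30, with a median of 0.53 (1.44-fold, adjusted p = 4.32e-08, and adjusted p = 0.751 with an estimated correlation), among them the chaperone genes MANF at 0.77 and PDIA4 at 0.76. Interferon response genes were higher for 26 of 29 (0.44, adjusted p = 2.41e-06, and adjusted p = 0.751 with an estimated correlation), such as IFIT3 at 0.88 and ISG15 at 0.53. Estradiol response genes were higher for 28 of 29 (0.45, adjusted p = 3.30e-06, and adjusted p = 0.751 with an estimated correlation), such as TFF3 at 1.24 and GREB1 at 0.39. Oxidative phosphorylation genes were higher for 39 of 45 (0.15, adjusted p = 0.00230, and adjusted p = 0.918 with an estimated correlation), for example NDUFB7 at 0.39. Proliferation genes were lower for 35 of 38 (−0.26, adjusted p = 0.0126, and adjusted p = 0.918 with an estimated correlation), for example CCNE2 at −0.97. All 6 calls were thus lost when camera estimated the correlation, and fry gave a lowest adjusted p of 0.974. No member of any list passed over all genes, and 0 passed when adjusted over the list alone, with or without the block.

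These list medians moved with a single array. With array weights the estradiol response list was at 0.03, the unfolded protein list at 0.09 and the proliferation list at 0.03. None of these 3 passed camera (adjusted p = 0.998, 0.308 and 0.998). That fit leaned on 1 array, with a weight of 12.9 for CK5+ replicate 3 and 0.165 for CK5− replicate 3. In it 5 lists passed camera, among them oxidative phosphorylation, whose median rose to 0.32 (adjusted p = 3.61e-08). CK5− replicate 3 correlated with the other 5 arrays of the sort at r of 0.946 to 0.956 across genes, and its own lists lay at −1.53 for unfolded protein and amino acid stress, −1.52 for estradiol response, −0.93 for ribosomal protein and −0.64 for interferon response against the mean of the other 5. By pair, the estradiol response median was −0.05, −0.00 and 1.31, the unfolded protein median 0.01, −0.01 and 1.61, the ribosomal protein median −0.10, 0.21 and 1.11, the interferon median −0.05, 0.09 and 0.87, the oxidative phosphorylation median −0.20, 0.21 and 0.49, and the proliferation median 0.01, 0.02 and −0.76. Within slide 1, which held pair 1, medians were therefore those of that pair, and within slide 2 they were 0.69 for estradiol response, 0.77 for unfolded protein, 0.67 for ribosomal protein, 0.51 for interferon, 0.33 for oxidative phosphorylation and −0.44 for proliferation. With the slide as a block all 6 lists passed, at adjusted p from 9.71e-16 for ribosomal protein to 0.00127 for proliferation. Without CK5− replicate 3, 3 lists passed: ribosomal protein (0.13, adjusted p = 5.19e-05), myeloid (higher, 0.19, adjusted p = 0.00332) and cholesterol synthesis (lower, −0.08, adjusted p = 0.0251). Without both arrays of replicate 3 only the myeloid list passed (0.13, adjusted p = 0.00878). The proliferation list turned to 0.15 without CK5− replicate 1 and to 0.18 without CK5+ replicate 2, and was no longer called without CK5+ replicate 3; the oxidative phosphorylation list was no longer called without CK5− replicate 2 or CK5+ replicate 1.

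The other 17 lists did not pass in the CK5 sort (adjusted p from 0.127 to 0.997). Markers of other epithelial states had medians of 0.10 for basal and myoepithelial, 0.11 for luminal and steroid receptor and 0.09 for cornified and squamous genes. Markers of other cell types lay at 0.01 for lymphoid, −0.01 for myeloid and 0.13 for fibroblast and endothelial genes. Stem and progenitor genes lay at −0.13, progesterone response genes at −0.12, retinoid genes at 0.12, Wnt genes at −0.04, Notch genes at 0.01, epithelial to mesenchymal genes at −0.02, histone genes at 0.06, cholesterol synthesis genes at 0.07, hypoxia and glycolysis genes at 0.00, immediate early and heat shock genes at 0.03 and NF-kB and cytokine genes at 0.00. The median, the mean and the test differed in sign for the hypoxia, immediate early, myeloid, NF-kB and Notch lists of this sort.

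In the CD28 sort, stress-induced and inflammatory genes stood lower in CD28+ than in CD28− cells. Immediate early and heat shock genes were lower for 36 of 37 members, with a median of −0.56, and NF-kB and cytokine genes for 23 of 27, with a median of −0.50; both calls by camera were lost with an estimated correlation (adjusted p = 0.146 and 0.483). Adjusted over the list alone, 11 of the 37 fell, among them the nuclear receptor gene NR4A1 (−1.59 ± 0.36), the chaperone gene HSPH1 (−1.42 ± 0.37), the stress transcription factor gene ATF3 (−1.21 ± 0.27, with 4 probes from −1.21 to −0.26) and the co-chaperone gene BAG3 (−0.95 ± 0.18). Adjusted over the list alone, 4 of the 27 fell, the chemokine genes CCL20 (−3.00 ± 0.79) and CXCL2 (−2.50 ± 0.38), TNFAIP3, an inhibitor of NF-kB signalling (−1.50 ± 0.33), and TNF (−1.32 ± 0.32). The NR4A1 and CCL20 probes were well above background on 1 of 3 CD28+ arrays each, so their differences are set partly against background. With the replicate block these counts adjusted over the list alone were 19 and 8. No member passed over all genes, with adjusted p of 0.985 to 0.996 by limma for these 8.

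Of 21053 genes, 0 passed the threshold by limma (lowest adjusted p = 0.985), and 1031 had an unadjusted p under 0.05, 312 higher and 719 lower in CD28+ cells, where chance would give 1053. The groups did not overlap for 2368 genes, or 11.2%, where chance gives 10%. Both chance values are again for unpaired arrays, and the other splits that part all 3 pairs gave at most 548 genes at an unadjusted p under 0.05. With the replicate block 0 genes passed (lowest adjusted p = 0.213, 2678 unadjusted). With array weights 2062 genes passed, 604 higher and 1458 lower, in a fit that gave CD28− replicate 2 a weight of 7.91 and CD28+ replicate 3 a weight of 0.211. With the slide as a block 1 gene passed, and without CD28− replicate 3 also 1, STMN4 (−4.69 ± 0.22, adjusted p = 0.0256), named after its value was seen.

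The named genes of the CD28 sort did not pass over all genes either (adjusted p from 0.985 to 0.996 by limma) and were chosen in the same way. CXCL2 (chromosome 4, 74962985 to 74963044, hg19) was 5.66-fold lower by the brighter of its 2 probes, with a smaller difference of the same sign by the other. FAM90A1 was at least 2.52-fold lower, PDE4B, a cyclic AMP phosphodiesterase gene, at least 2.24-fold and LAYN, a hyaluronan receptor gene, at least 1.44-fold. DNAJB3, a transcribed pseudogene, stood at −2.43 ± 0.38 with its probe well above background on 1 of 3 CD28+ arrays, the glutamate transporter gene SLC1A3 at −1.55 ± 0.26, CSRNP1 at −1.37 ± 0.21, JMJD6 at −1.19 ± 0.18 and H2AC25 at −1.18 ± 0.22. Among genes higher in CD28+ cells, RGS11, a regulator of G protein signalling (chromosome 16, 318324 to 318383, hg19), was 2.00-fold higher (1.00 ± 0.17). TMC4 stood at 0.94 ± 0.18, the ectonucleotidase gene ENTPD8 at 0.97 ± 0.22, SAPCD1 at 0.87 ± 0.19, the phosphatase gene PPM1J at 0.85 ± 0.16 and the ceramide synthase gene CERS1 at 0.83 ± 0.18. PYGO1, a coactivator of Wnt signalling, stood at 0.75, the dynein docking gene ODAD1 at 0.72 and SAMD10 at 0.70. MDGA1 stood at 1.52 by its brighter probe and 0.08 by its other.

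**Figure D3:**
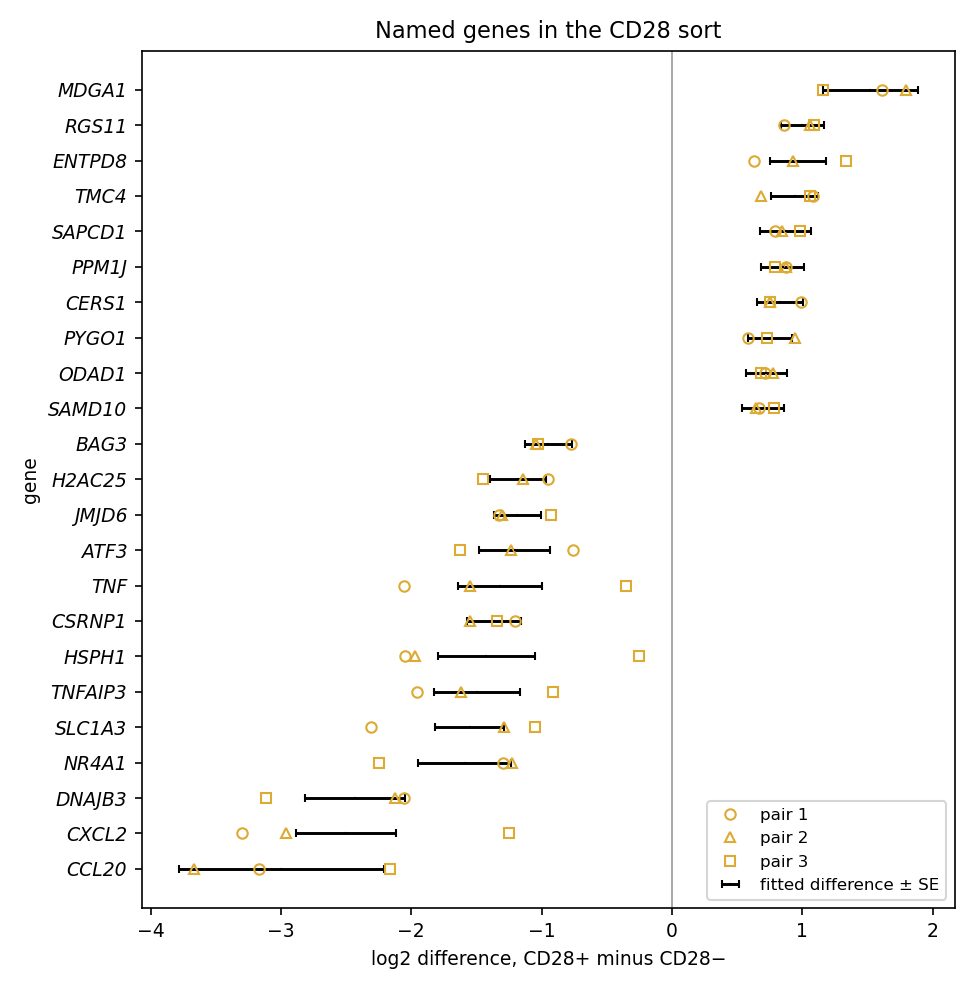
Log2 differences (CD28+ minus CD28−) of the named genes of the CD28 sort that were well above background on at least 1 array of each group, with the fitted value ± SE in black and the 3 pairs as open symbols. Among genes well above background on all 6 arrays, CXCL2 lies lowest at −2.50 and MDGA1 highest at 1.52.

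Lists passing camera at the preset correlation in the CD28 sort numbered 13 of 23, 2 higher and 11 lower in CD28+ cells. The immediate early and heat shock list had an adjusted p of 6.75e-17, and adjusted p = 0.146 with an estimated correlation; fry gave an adjusted p of 0.0516 for movement one way and 0.00568 for movement in either direction. Its median was −0.48, −0.66 and −0.64 in pairs 1, 2 and 3, −0.60 within slide 3 and −0.64 within slide 4, with adjusted p = 3.17e-14 with the slide as a block. The NF-kB and cytokine list had an adjusted p of 1.76e-07, and adjusted p = 0.483 with an estimated correlation; fry gave adjusted p = 0.341 one way and 0.176 in either direction, and no list of this sort passed fry for movement one way. Its median was −0.90, −0.61 and −0.15 in the pairs, −0.77 within slide 3 and −0.15 within slide 4, and with the slide as a block its adjusted p was 1.53e-07. With normexp its median was −0.11. Of the 13 calls, these 2 and the retinoid list passed whichever single array was left out, though the retinoid list no longer passed with array weights (−0.20, adjusted p = 0.125); 7 of the 13 still passed without CD28− replicate 2 and 5 without CD28+ replicate 1.

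Epithelial and developmental groups were among the lists lower in CD28+ cells. Basal and myoepithelial genes were lower for 20 of 31 (median −0.35, adjusted p = 0.00938, and adjusted p = 0.626 with an estimated correlation), for example the crystallin gene CRYAB at −1.70 and KRT6A at −1.20. Cornified and squamous genes were lower for 28 of 36 (−0.26, adjusted p = 0.00494, and adjusted p = 0.529 with an estimated correlation), for example IVL, the cornified envelope gene involucrin, at −1.30 and SPRR2A at −1.09. Within slide 3 the medians of these 2 lists were −0.51 and −0.33, and within slide 4 −0.01 and 0.06; with normexp they were −0.05 and −0.05, where the basal list no longer passed (adjusted p = 0.0910), and neither passed without CD28+ replicate 1. Epithelial to mesenchymal genes were lower for 17 of 24 (−0.20, adjusted p = 0.0121, and adjusted p = 0.626 with an estimated correlation), for example SNAI1 at −1.03, with −0.30 within slide 3 and 0.16 within slide 4, and with normexp their median turned to 0.02 and the list no longer passed (adjusted p = 0.146). Retinoid genes were lower for 17 of 21 (−0.16, adjusted p = 0.00938, and adjusted p = 0.370 with an estimated correlation), for example RARRES1 at −1.38 and CYP26A1 at −1.21, with −0.20 within slide 3 and −0.36 within slide 4. Progesterone response genes were lower for 25 of 38 (−0.19, adjusted p = 0.0178, and adjusted p = 0.529 with an estimated correlation), for example the kinase gene SGK1 at −1.50 and the clock gene PER1 at −0.91, with −0.13 within slide 3, where the list no longer passed (adjusted p = 0.297), and −0.26 within slide 4. Stem and progenitor genes had a median of −0.02, or 0.02 with normexp and 0.01 with median scaling (adjusted p = 0.0378, and adjusted p = 0.626 with an estimated correlation), lower for 16 of 29. They no longer passed with the replicate block (adjusted p = 0.0661) or the slide block (adjusted p = 0.0850), and lay at −0.09 within slide 3 (adjusted p = 0.165) and 0.01 within slide 4.

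Metabolic, hormone and cell cycle groups made up the rest. Hypoxia and glycolysis genes were lower for 27 of 31 (−0.31, adjusted p = 0.00938, and adjusted p = 0.715 with an estimated correlation), for example ADM at −1.13, with −0.18 within slide 3, where the list no longer passed (adjusted p = 0.305), and −0.53 within slide 4. Cholesterol synthesis genes were lower for 21 of 29 (−0.15, adjusted p = 0.00938, and adjusted p = 0.715 with an estimated correlation), for example HMGCS1 at −0.64, with −0.17 within slide 3, where the list no longer passed (adjusted p = 0.0770), and −0.16 within slide 4. Oxidative phosphorylation genes were lower for 32 of 45 (−0.11, adjusted p = 0.0401, and adjusted p = 0.715 with an estimated correlation). They no longer passed with the replicate block (adjusted p = 0.0597) or the slide block (adjusted p = 0.0595), and lay at −0.05 within slide 3 (adjusted p = 0.762) and −0.25 within slide 4. Proliferation genes were higher for 32 of 38 (0.47, adjusted p = 0.0121, and adjusted p = 0.715 with an estimated correlation), for example TOP2A at 1.46 and RRM2 at 1.13. Their median was −0.16, 0.63 and 0.81 in the pairs and 0.30 within slide 3, where the list no longer passed (adjusted p = 0.0770), and turned to −0.32 without CD28+ replicate 3 and −0.06 without CD28− replicate 1. With normexp it was 0.36 and the list no longer passed (adjusted p = 0.126). Estradiol response genes were higher for 22 of 30 (0.25, adjusted p = 0.00938, and adjusted p = 0.703 with an estimated correlation), for example IGFBP5 at 0.66. Their median was 0.64, 0.33 and −0.30 in the pairs and 0.49 within slide 3, and with normexp it was 0.22 and the list no longer passed (adjusted p = 0.0526). With the replicate block 11 lists passed camera at the preset correlation, and 0 with an estimated correlation (lowest adjusted p = 0.661). Counts adjusted over the list alone were 0 for the 11 lists other than immediate early and NF-kB, and with the replicate block 5 for hypoxia, 5 for retinoid, 4 for progesterone response, 3 for epithelial to mesenchymal and 2 for cornified.

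Several of these calls of the CD28 sort rested on single arrays. Without CD28− replicate 2 the medians of lists that no longer passed were 0.03 for hypoxia, −0.18 for epithelial to mesenchymal, −0.13 for progesterone response, 0.21 for estradiol response, 0.44 for proliferation and −0.05 for stem genes. Without CD28+ replicate 1 they were 0.06 for hypoxia, −0.07 for epithelial to mesenchymal, −0.04 for cholesterol synthesis, 0.18 for estradiol response, 0.01 for oxidative phosphorylation, −0.01 for stem, −0.19 for basal and −0.17 for cornified genes. Without CD28− replicate 3 they were −0.30 for hypoxia, −0.05 for cholesterol synthesis, 0.10 for oxidative phosphorylation and −0.13 for stem genes. Without CD28+ replicate 3 they were −0.34 for hypoxia, −0.00 for progesterone response, −0.32 for proliferation and −0.12 for stem genes. The estradiol list also no longer passed without CD28− replicate 1 (0.10), and the proliferation list without CD28− replicate 1 (−0.06) or CD28+ replicate 2 (0.31).

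The other 10 lists did not pass in the CD28 sort (adjusted p from 0.0770 to 0.397). Markers of other cell types lay at 0.07 for lymphoid, −0.11 for myeloid and −0.11 for fibroblast and endothelial genes. Luminal and steroid receptor genes lay at 0.11, interferon response genes at 0.15, unfolded protein and amino acid stress genes at 0.06, ribosomal protein genes at 0.03, histone genes at −0.02, Notch genes at −0.06 and Wnt genes at −0.13. Adjusted over the list alone, 0 members of these lists passed, and with the block 2 of the luminal and 2 of the Notch list. The median, the mean and the test differed in sign for the histone and unfolded protein lists. In the fixed panel, KRT6A differed by −1.20 ± 0.50, KRT17 by −0.37 ± 0.25, KRT14 by 0.04 ± 0.49 and TP63 by −0.11 ± 0.36. CD44 differed by 0.56 ± 0.25, EGFR by −0.35 ± 0.30, MKI67 by 0.63 ± 0.86, ESR1 by 0.16 ± 0.33 and PGR by 0.29 ± 0.35. The luminal keratins KRT8, KRT18 and KRT19 differed by 0.18, −0.06 and 0.11. The 3 probes of EGFR ranged from −0.49 to 0.28 and those of KRT8 from −0.37 to 0.18. Each had an adjusted p of 0.999 by limma.

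**Figure D4:**
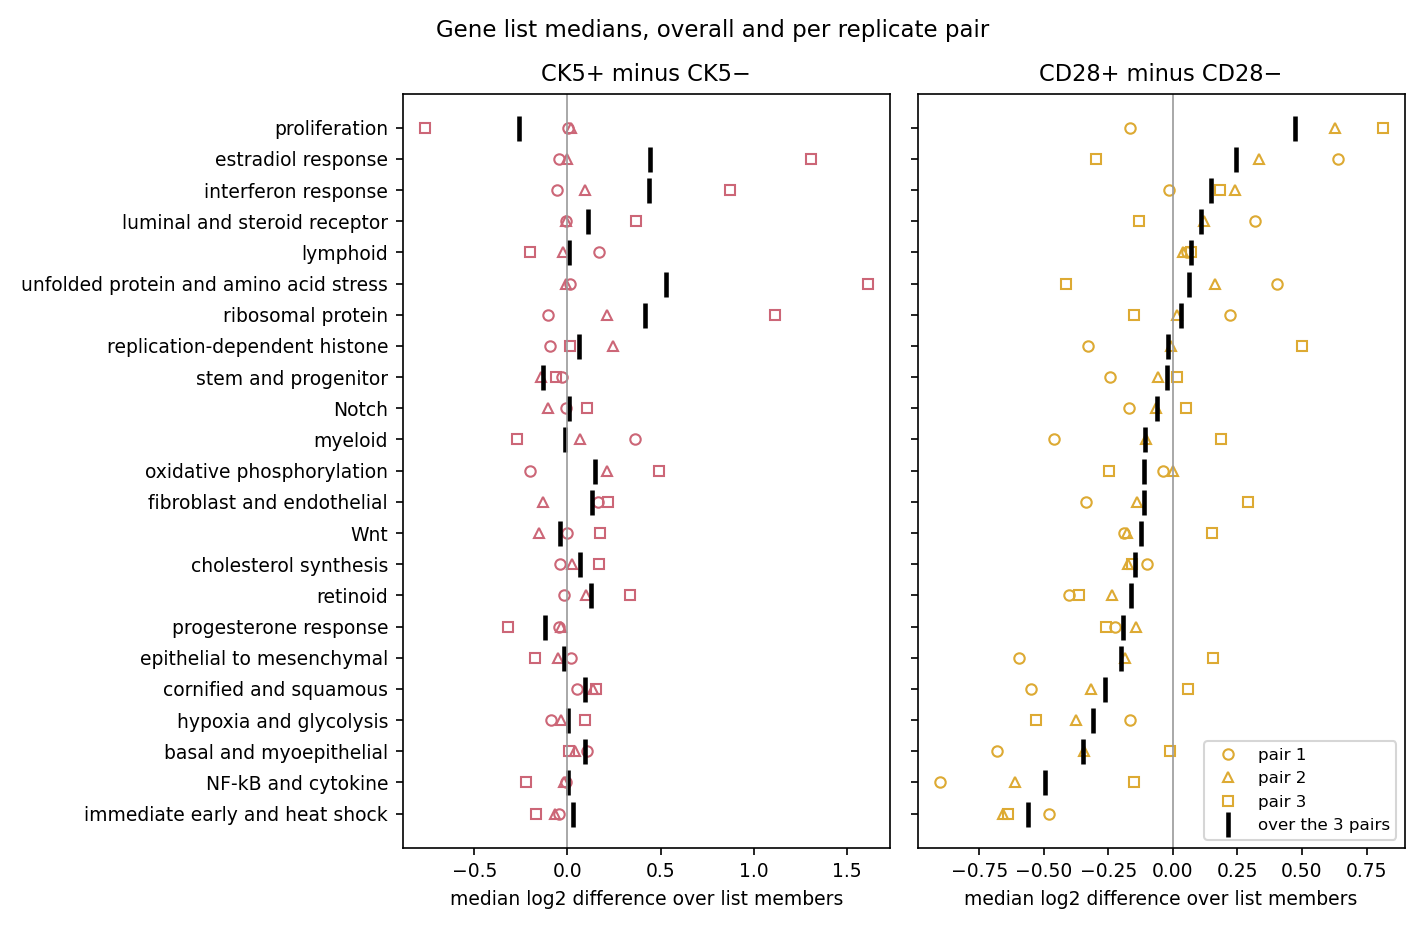
Median log2 difference over the members of each of the 23 gene lists in the CK5 and the CD28 sort, over all arrays (black bars) and in each of the 3 pairs (open symbols). The immediate early and heat shock list lies below 0 in all 3 CD28 pairs (−0.48, −0.66 and −0.64), while the unfolded protein and estradiol lists of the CK5 sort lie near 0 in pairs 1 and 2 and at 1.61 and 1.31 in pair 3.

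The sorts were compared to ask whether CK5+ and CD28+ cells departed from their negative counterparts in the same genes. The sorts also differed in cell preparation (permeabilized and fixed against enzymatically dissociated), in slides and in Feature Extraction version. A difference between their effects can therefore not be assigned to the markers alone. Over the 17507 genes kept in both, the log2 differences correlated at Pearson's r of 0.0935 and Spearman's rho of 0.0818, and 52.6% of genes had the same sign. This is a correlation across genes, which are not independent replicates; single pairs of the sorts combined gave r from −0.161 to 0.226. By the interaction contrast, 0 of 21417 genes differed between the sorts by limma (lowest adjusted p = 0.999, 407 at an unadjusted p under 0.05 where chance gives 1071). With the replicate block limma also called 0 (lowest adjusted p = 0.672, 1305 at an unadjusted p under 0.05). The chance value is again for unpaired arrays, and pairs that deviate together lower the count without the block. Without CK5+ replicate 2 the contrast called 2 genes, CPS1-IT1 and GSPT2, named after their values were seen (lowest adjusted p = 0.00273); both were well above background on fewer than 3 of the 6 CK5 arrays, so no difference is given. As lists, 11 of 23 (10 over the genes kept in both sorts) differed between the sorts by camera at the preset correlation, led by ribosomal protein genes, 0.39 higher in the CK5 effect (adjusted p = 4.26e-09, and adjusted p = 0.732 with an estimated correlation), and immediate early and heat shock genes, 0.50 higher (adjusted p = 1.35e-08, and adjusted p = 0.179 with an estimated correlation). The CK5 effect of ribosomal protein genes rested largely on CK5− replicate 3, with a median of 0.42, or 0.13 without that array. The contrast of lists was not run without it.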

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

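Of the tests in this part, those of the KRT5 probe, of weak signal on CK5− replicate 3, and of single pairs and of handling for the immediate early list were chosen only after the result was seen.

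The effects of the 2 sorts differed for 11 of 23 gene lists by camera on the interaction contrast at the preset correlation; none held with an estimated correlation (lowest adjusted p = 0.179). Given as the median over members of the CK5 effect minus the CD28 effect (log2), 10 of the 11 were higher in the CK5 sort. These were ribosomal protein at 0.390, immediate early and heat shock at 0.502, NF-kB and cytokine at 0.617, cornified and squamous at 0.615, basal and myoepithelial at 0.500, unfolded protein and amino acid stress at 0.496, retinoid at 0.372, myeloid at 0.347, hypoxia and glycolysis at 0.318 and oxidative phosphorylation at 0.265. The proliferation list was lower, at −0.901. Part of these differences rested on CK5− replicate 3. Without that array the CK5 median fell from 0.42 to 0.13 for ribosomal protein, from 0.53 to 0.04 for unfolded protein and from 0.15 to 0.05 for oxidative phosphorylation genes. For proliferation genes it moved from −0.26 to −0.16. The CD28 effects leaned on single arrays or slides too. Without each array in turn the proliferation median ranged from −0.32 to 1.28 in the CD28 sort and from −0.82 to 0.18 in the CK5 sort. The CD28 medians of the basal and cornified lists were −0.51 and −0.33 within slide 3, and −0.01 and 0.06 within slide 4. Those of the immediate early list were −0.60 and −0.64. The contrast of lists was not run without CK5− replicate 3. Cell preparation, slides and Feature Extraction version also differed between the sorts, so these differences cannot be assigned to the markers alone. Some members of the 11 lists were not well above background in the CK5 sort. Over the 17507 genes kept in both sorts, a choice made after seeing the data, 10 lists passed, 9 of them among the 11; the basal (0.496, adjusted p = 0.146) and myeloid (0.0656, adjusted p = 0.603) lists did not.

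KRT5 transcript was not well above background on any of the 6 arrays of cells sorted for the CK5 protein, while 2 of 3 CD28− arrays detected it. On the CD28− arrays that detected it, KRT5 had a mean level of −4.66. Of probes within 0.25 log2 of that level on a CK5 array, at least 84.5% were well above background, on every CK5 array. A KRT5 signal of that level would thus mostly have been detected there. That level lay above the lowest detected signal of each CK5 array, so a high share was near certain beforehand. The test cannot show whether a detection limit hid a lower signal in the fixed cells. A probe that does not report KRT5 stays open, since it was well above background on 2 of the 12 arrays, and a fault in the probe and a true low level cannot be told apart with so few detections. Loss of the transcript in the fixed cells and a low transcript level in CK5+ cells were not tested.

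CK5− replicate 3 stood apart from the other 5 arrays of its sort: 1573 of 17683 genes lay more than 2-fold outside the range of the other 5, against at most 133 for any other array. Weak signal is argued against by its 4421 brightest genes, whose median deviation was 1.86 times the largest of the other arrays, and blood, stromal or endothelial cells by the count of their abundant transcripts over 1 log2 unit above the other 5, which was 0 of 23. In the other direction, IGFBP7, PTPRC, VIM and CORO1A lay 1.72, 1.44, 1.15 and 1.14 above the mean of the other 5, DCN and COL3A1 1.29 and 1.25 above it without being well above background, and the lymphoid and myeloid lists at 0.43 and 0.49, above every other array, while CD74, SRGN and FN1 were not well above background on it. A loss of cytoplasmic RNA in that library may account for part of the pattern, but stays open. For it, 7 nuclear-retained RNAs had a median deviation of 0.593 (0.28 at most on another array, −0.57 at least), with 2 of them lower (OIP5-AS1 at −0.75 and MEG3 at −0.26). Ribosomal protein genes had one of −0.93, and long noncoding RNAs 0.39 against −0.02 for protein-coding genes. Other mRNAs were not lost alike. The oxidative phosphorylation (−0.30) and hypoxia and glycolysis (−0.13) lists lay within the range of the other arrays, and proliferation genes at 0.42. Each of the other arrays was set against a mean that includes CK5− replicate 3, which widens its gap to them in these comparisons. Another epithelial population or line was not tested. No biological explanation was tested, because no label sets this sample apart from its group.

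Immediate early and heat shock genes were lower in CD28+ cells by camera at the preset correlation, a call lost with an estimated correlation (adjusted p = 0.146). Their expression level is argued against as the cause, since the list median lay at percentile 0 of 10000 random lists of matched level, whose lowest median was −0.22, and so is a single replicate pair, since the highest of the 3 pair medians was −0.481. Handling or sorting that differed between the gates stays open: the list was lower in 3 of 3 pairs, each pair holds 1 array of each gate, and stress in dissociated cells cannot be told apart from the gate. A difference between CD28+ and CD28− cells in culture, the biological explanation that the design names, was not tested.

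Other splits of the arrays were counted for each number of calls. With 3 arrays against 3 there are 10 splits of a sort, too few for a share under 0.05. Against a real count of 0 genes all 10 splits of either sort gave as many by construction, so these counts say nothing about chance. The highest other split of the CK5 sort gave 1165 genes, which points to a structure of the samples apart from the gates: that split set both arrays of slide 1 and CK5− replicate 3 against the rest, and was not fitted with the slide as a block. The real split gave 0 genes with that block (lowest adjusted p = 0.922), as it did without. For lists in the CK5 sort 8 of 10 splits gave as many as the real 6, with 9 the highest other. The highest other split of the CD28 sort gave 0 genes, and 4 of 10 gave as many lists as the real 13, with 14 the highest other. Of the 4 splits of the CD28 sort that part all 3 pairs, the real one had 1031 genes at an unadjusted p under 0.05 against at most 548 in the others, and 13 lists against at most 13; in the CK5 sort these were 95 genes against at most 105, and 6 lists against at most 6. The immediate early list median of the CD28 sort had a size of 0.56 in the real split and at most 0.36 in the other splits of that sort. The NF-kB list median had one of 0.496 in the real split and 0.500 in another. Both lists were looked at because they had the lowest adjusted p in the real split. A larger size there was thus partly built in and is not independent support. For the interaction, 100 of 100 regroupings within the sorts gave as many genes as the real 0, which was certain, so this count says nothing about chance.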

How the results depend on the processing

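Of the settings in this part, leaving out both arrays of a replicate number and, for the lists, median scaling, the stricter filter, array weights, the deposited table, slides, single arrays left out the block with an estimated correlation and genes kept in both sorts were chosen after seeing the data. The cause of each change below was not tested, except that fewer arrays were fitted where arrays were left out.

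The count of 0 genes in the CK5 sort held under all 17 other settings by limma (42 to 682 at an unadjusted p under 0.05, lowest adjusted p = 0.0591 with all 12 arrays in 1 fit) and without each array in turn (29 to 548). In the CD28 sort it was 1 with the slide as a block, 2062 with array weights and 0 under the other 15 settings, and 0 to 1 without each array. The interaction gave 0 to 2 genes without each array, and the correlation of the 2 effects was 0.0115 to 0.199. No scaling moved the median of all genes by over 0.1, the largest shift being 0.07 with normexp in the CD28 sort. No named gene had a call to lose or reverse; under other settings 31 values in the CD28 sort passed the threshold, and 43 in the CD28 and 40 in the CK5 sort changed sign.

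Lists past the threshold fell from 6 to 0 in the CK5 sort and from 13 to 0 in the CD28 sort with an estimated correlation (lowest adjusted p = 0.751 and 0.146), and also to 0 and 0 with the replicate block and an estimated correlation (0.779 and 0.661). With normexp 9 lists passed in the CD28 sort, since it ended the basal, epithelial to mesenchymal, estradiol and proliferation calls. The oxidative phosphorylation list also no longer passed with quantile normalization in the CK5 sort (0.109, adjusted p = 0.0762) and with median scaling in the CD28 sort (−0.0808, adjusted p = 0.0683), and in either sort with no filter (adjusted p = 0.0571 and 0.0585) and in the CK5 sort with the deposited table (0.0754). With array weights the estradiol (0.0290), unfolded protein (0.0949) and proliferation (0.0254) lists of the CK5 sort and the hypoxia (−0.410), progesterone (−0.151), retinoid (−0.203) and stem (−0.0861) lists of the CD28 sort no longer passed. Within slide 3 the hypoxia, cholesterol, progesterone, proliferation, stem and oxidative phosphorylation calls of the CD28 sort were lost. The stem list was also lost with no filter and with the stricter filter, and the basal list with the stricter filter (−0.237). Without each array in turn they numbered 3 to 9 in the CK5 sort and 6 to 13 in the CD28 sort, and without both arrays of replicate 3 in the CK5 sort 1. Of the lists named below, the medians without each array in turn ranged from −0.0572 to 0.746 for estradiol, 0.0547 to 0.348 for oxidative phosphorylation and −0.821 to 0.175 for proliferation in the CK5 sort, and from −0.270 to 0.105 for oxidative phosphorylation and −0.323 to 1.28 for proliferation in the CD28 sort. The replicate block changed no call other than the oxidative phosphorylation and stem lists of the CD28 sort. In the CK5 sort the proliferation list reversed without CK5− replicate 1 (0.147) and without CK5+ replicate 2 (0.175), the estradiol list without CK5− replicate 3 (−0.0572), and, without both arrays of replicate 3, the test reversed for the estradiol (0.00499) and oxidative phosphorylation (0.00596) lists. In the CD28 sort the proliferation list reversed without CD28− replicate 1 (−0.0585) and without CD28+ replicate 3 (−0.323), and oxidative phosphorylation without CD28− replicate 3 (0.105). The test of that list also reversed within slide 3 and without both arrays of replicate 3 (−0.0537 each) and with array weights (−0.0282), where its median stayed below 0.

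Signal over background limits what the CK5 arrays can show: KRT5 and 4 genes of the fixed panel were detected on fewer than 3 of 6 arrays. On data simulated with the pair structure, limma without the block recovered 0% of 2-fold changes in either sort, and without that structure 0.4% and 1.6%, so a count of 0 does not speak to changes of that size.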

Other observations

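The values in this part were chosen after the data were seen, and no explanation was tested for them. On CK5− replicate 3, genes that were high on the other 5 arrays of the sort lay far lower, among them LAMP3, a lysosomal membrane protein gene, at −5.18 (log2, against the mean of the other 5), CALCR, the calcitonin receptor gene, at −4.68, LRRN3 at −4.62 and the cystine transporter gene SLC7A11 at −3.99. Genes far higher on that array were TRPM8, a cold-sensing channel gene, at 4.51, SGK1, a kinase gene induced by corticosteroids and progesterone, at 4.37, the water channel gene AQP3 at 3.98 and the thioredoxin inhibitor gene TXNIP at 3.64. The progesterone response list lay at 0.38 on that array and between −0.31 and 0.18 on the others. Of its members named here, SGK1 was higher and CALCR lower. Further lists also lay above every other array: myeloid (0.49), lymphoid (0.43), epithelial to mesenchymal (0.42), immediate early and heat shock (0.33), NF-kB and cytokine (0.32) and stem and progenitor (0.22). The rise was therefore not particular to progesterone response genes. The estradiol response list lay at −1.52 on that array and between 0.20 and 0.38 on the others. In these list values each array was set against the mean of its own other 5. For the others that mean includes CK5− replicate 3, which moves their values away from it and widens each gap. The 0.20 to 0.38 is therefore not to be read as a rise on those arrays. The ESR1 and PGR levels of CK5− replicate 3 were 0.27 and 1.49, against at least 1.75 and 4.32 on the other 5.

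Proliferation genes varied more between replicate numbers than between gates. In the CD28 sort the list's median deviation from the 6-array mean was −1.50, −0.26 and 1.02 on CD28− replicates 1, 2 and 3, and −1.50, 0.48 and 1.84 on the CD28+ replicates with those numbers. In the CK5 sort it was 1.01, −0.95 and 0.35 on the CK5− replicates and 1.00, −0.92 and −0.43 on the CK5+ replicates. Hypoxia and glycolysis genes in the CD28 sort likewise lay at −0.56, 0.85 and 0.36 on the CD28− arrays and at −0.90, 0.42 and −0.31 on the CD28+ arrays.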
